A study of Oryza sativa with 6 samples.

How the data were processed

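Roots of etiolated rice seedlings were profiled on 6 Affymetrix rice arrays, 1 each for WT, mhz2 and mhz8 in air and in ethylene. Per the labels, seeds germinated at 37 °C for 2 days, seedlings were 3 days old at treatment, ethylene was 10 ppm for 8 h at 28 °C in the dark, and biotin-labelled cRNA was made from 6 µg of total RNA. The labels also say that the water level was lowered for the ethylene treatment; whether the same was done in air is not given in the sources used here. The submitters' processing notes credit the values to MAS5 and give no version. The deposited values were read as probe set signals on a linear intensity scale from their range, since the notes do not state the scale. The scaling parameters are not given in the sources used here, and the authors' intensity values were used as deposited, with no further normalization. Each array's column was matched to its group through the labels, and 0 columns belonged to no sample.

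The array held 57381 probe sets, of which 123 were controls and were left out of all counts. The annotation table gave 1 gene for 22436 probe sets, several for 95 and none for 34727, and all gene identifiers matched the reference gene table, which was used only for names. No gene was named from a probe set with several genes. Of 17905 genes, 2457 had a usable name, on 3192 probe sets. No coordinates were used.

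Choices of tests, gene lists and alternatives were made before the data were examined, except where stated. On each array a floor T was set at 0.2 times the mean signal after removing 2% at each end. Signals below T were raised to T, and a probe set counted as measured in a comparison when at least 1 of the 2 arrays reached T. Of all probe sets, 22674 reached T on all 6 arrays and 26950 on at least 1. With 1 array per group, comparisons of 2 arrays are log2 ratios with no p-value, and probe sets at least 2-fold apart were counted. A fold against a signal below T is a lower bound and is written as "at least". Three-genotype comparisons were the correlation of ethylene responses across probe sets and the response, in the remaining genotypes, of probe sets chosen in one genotype.

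Tests used limma 3.58.1 in R 4.3.3 on log2 signals of the 25805 probe sets at or above T on at least 2 arrays, with an intensity trend and Benjamini-Hochberg adjustment at 0.05. The additive fit had terms for genotype and treatment and 2 residual degrees of freedom. In it the genotypes stand as the repeats of the treatment and the treatments as the repeats of the genotype, so its error holds array noise and any interaction. A further fit added the response of 1 genotype against the others, taken as alike, and had 1 residual degree of freedom. The p-values measure the spread between these arrays only. Data were simulated with the real signals and 200 changed probe sets. The additive fit for ethylene recovered 64.5% at a log2 change of 1 (10 false calls) and 99.5% at 2 (20 false calls). The fit for the WT response recovered 0.5% at 1 (1 false call) and 54% at 2 (108 true and 26 false calls). The simulated noise used spreads that limma had already drawn towards each other, so these shares may be too high for the real arrays. They do not show that real changes of this size would have passed. In each of these runs the false calls made up a larger share of all calls than the 0.05 aimed at. Adjusted p-values may therefore be too small, most of all for the WT response.

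The 40 gene lists had been written as patterns on gene descriptions. The tables given hold symbols and no descriptions, so the patterns were turned into symbol patterns after the name tables were seen and before any value by list was looked at, and "a gene description" in the naming rule became "a gene name". Each gene was represented by its brightest probe set, with members below T held at T. A list's median log2 ratio was set among 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these arrays, for lists with at least 3 measured members (31 lists in WT). Members past the limma threshold were counted over all genes tested and adjusted over the list alone. A check used mhz2 ethylene against air and 100 simulated lists of 15 genes that reached T on all 6 arrays. With no shift 4 lay outside the middle 95%, and with a shift of 0.5 all 100 lay above it. This does not carry over to WT, where log2 ratios had an SD of 0.67 against 0.32 in mhz2, or to shorter lists. For the GH3 list in WT, with 6 measured members, the middle 95% reached 0.61, so a shift of 0.5 could be missed. In the heat shock list, ARD1 enters through a shared synonym.

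Genes were named by a fixed rule. For the ethylene comparison of each genotype and each mutant against WT in air, these were the 10 highest and 10 lowest log2 ratios among genes with a name and a signal of at least 5 T. Up to 4 members per list with the largest WT ethylene ratio and a signal of at least 2 T were added, as were the ethylene receptors, EIN2 and EIL1. The part of the rule on the average ethylene effect named no gene, since none passed. The rule also asked for SOR1, for which the tables pair no probe set. Where comparisons shared the WT array, 100 pairs of unchanged groups were simulated against a shared array, and the overlap of independent lists was computed.

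Alternatives were quantile normalization, median centring, floors at 0.1 and 0.4 of the trimmed mean, a pseudocount of 0.05 of it in place of a floor, no filter, no intensity trend, leaving out each genotype in turn, and the mean over a gene's probe sets. One floor for all arrays was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for the rest.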

Results

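Transcript levels were measured in the roots of dark-grown rice (Oryza sativa) seedlings of 3 genotypes, the wild type (WT) and the ethylene-response mutants mhz2 and mhz8. Seedlings of each genotype were kept at 28 °C in air or in 10 ppm ethylene, the ethylene for 8 h. For the air seedlings the labels give no number of hours. RNA from the roots was hybridised to a 1-colour Affymetrix rice array. There were 6 arrays, 1 for each genotype and treatment, each labelled as a biological replicate 1, so no difference between 2 arrays had a replicate check and none was given a p-value. The design names shoots as well as roots; shoots were not analysed here. Of 57258 probe sets other than controls, between 24537 and 24906 per array reached the floor T, a signal of 24.5 to 24.9 below which a signal was treated as not measured. The arrays had close signal distributions, with a median ratio of 1.03 and a highest ratio of 1.12 between any of them at the same rank. The ratio of the 3' to the 5' actin probe sets, a sign of RNA integrity, differed between arrays. It was 4.90 in WT air and 9.79 in WT ethylene, 8.98 in mhz2 air and 5.28 in mhz2 ethylene, and 6.36 in mhz8 air and 13.5 in mhz8 ethylene. The Gapdh ratio ran from 7.22 in mhz2 ethylene to 14.5 in mhz8 ethylene, so 3' signals were well above 5' signals on every array. The series concerns ethylene responses and yield traits in the mutants, and the comparisons below ask how roots of each genotype differed between ethylene and air and how the mutants differed from the WT. MHZ2 is known to be SOR1, a ubiquitin ligase. The name tables used here pair no probe set with MHZ2 or MHZ8, so the mutated genes gave no check of the labels.

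In WT roots, the named genes furthest above air in ethylene included genes of iron uptake and germin-like proteins and single genes of diterpenoid phytoalexin synthesis. DXPS (LOC4342614), a 1-deoxyxylulose 5-phosphate synthase that feeds plastid isoprenoid synthesis, was 27.9-fold higher, from a signal of 24.9 in air, just above T, to 696 in ethylene. The germin-like gene GLP2 (LOC4344846) was 19.9-fold higher, the syn-copalyl diphosphate synthase CPS4 (LOC4335090) 19.2-fold, and its cluster neighbour CYP99A3 (LOC4335091), a cytochrome P450 of momilactone synthesis, 15.5-fold. CYP99A2 and the germin-like gene GER7, both under T in air, were each at least 10.4-fold higher, and JAMYB, a jasmonate-inducible MYB factor, at least 8.92-fold. YSL15, a transporter of iron bound to deoxymugineic acid, was 9.77-fold higher, NAAT1, an enzyme of mugineic acid synthesis, 7.91-fold, and the defence protein gene PBZ1 went from a signal of 183 in air to 1464 in ethylene. The largest decreases among named genes were in the dehydrin RAB21 (13.4-fold lower), the small helix-loop-helix gene ILI2 (at least 11.4-fold), the arginine decarboxylase ADC2 (11.4-fold) and ILI6 (6.28-fold). LEA19 was 5.79-fold lower, RAB16D 5.36-fold, Chib3H-h 5.10-fold, CRSH2, which makes the alarmone ppGpp, 4.69-fold, PM1 4.58-fold, and the calcium pump ACA5 4.41-fold.

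By gene list, the clearest group in WT was iron uptake and chelation. All 14 measured members were higher in ethylene, 10 of them at least 2-fold, and the median log2 ratio of 2.05 lay above all 10000 random lists of the same size and signal. NAS3 and NAS1, which make nicotianamine, had log2 ratios of 2.88 and 2.66. All 7 germin-like genes were higher, 4 of them at least 2-fold, with a median of 1.45, also above all random lists. The LEA and dehydrin list went the other way, with a median of -1.80 and 5 of 7 members at least 2-fold lower. It lay below all random lists. The ABA metabolism list had a median of -0.89 (percentile 0.01), with the ABA 8'-hydroxylases ABA8OX1 at -1.05 and ABA8OX2 at -1.14, MHZ4 at -0.99 and the phytoene synthase PSY2 at -0.89. The cell cycle list had a median of -0.49 (percentile 0.02) over 24 genes, with CYCD6-1 at -1.12, CYCD5-3 at -1.04 and OsMCM6 at -0.83, while CYCD5-2 stood at 0.96.

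Hormone lists other than ABA were mixed in WT. The ethylene signalling list had a median of 0.55 (percentile 98.9), led by the receptor ETR2 at 1.76, while ERS2 stood at 0.67, ERS1 at 0.55 and ETR3 at -0.23. ETR4 was below T on every array. EIL1A, the main transcription factor of the pathway, stood at 0.69 and EIN2, which passes on the signal, at -0.18. Type-A response regulators, which are induced by cytokinin, had a median of -0.42 (percentile 3.53) with RR6 at -0.97 and RR9 at -0.95. Genes of cytokinin metabolism had a median of 0.79 (percentile 99.3), and LOGL1, a cytokinin-activating enzyme, stood at 2.18. Aux/IAA repressors had a median of 0.20 (percentile 98.8), with IAA20 at 2.31, and the GH3 enzymes that conjugate auxin 0.56 (percentile 96.6), with GH3.2 at 1.99. Auxin response factors (-0.01, percentile 64.7), auxin synthesis (0.10, percentile 66.6) and auxin transport (0.23, percentile 71.9) stood close to random lists, as did heat shock genes (0.08, percentile 80.3). The jasmonate list had a median of 0.13 (percentile 97.6), with OPR-1 at 2.21 and the repressor gene JAZ12 at 1.76.

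Transport and defence lists were mostly higher in WT ethylene. Phosphate transport and starvation genes had a median of 0.74 (percentile 99.8), with PHT1-1 at 1.63, and nitrogen transporters 0.61 (percentile 99.0), with the ammonium transporter AMT3-3 at 1.55. CASP and CASP-like genes, used as endodermis markers, had a median of 0.44 (percentile 99.8), with OsCASPL1U2 at 2.51. Aquaporins had a median of 0.17 (percentile 99.1), with the silicon channel Lsi1 at 2.28 and PIP2-8 at -1.11. WRKY factors had a median of 0.91 (percentile 99.0), NAC factors 0.84 (percentile 99.0), pathogenesis-related genes 0.41 (percentile 98.4) and glutathione transferases 0.56 (percentile 98.5). Expansins, which loosen cell walls, had a median of -0.39 (percentile 0.26), yet EXPA6 was at least 2.89 higher on the log2 scale and EXPB7 stood at 1.60, while EXPA8 stood at -1.69 and EXPA31 at -1.29. Ribosomal proteins had a median of -0.31 (percentile 2.13). Cellulose synthases (-0.31, percentile 6.76), lignin and phenylpropanoid genes (0.13, percentile 96.0), fermentation genes (0.44, percentile 95.5), class III peroxidases (0.11, percentile 82.0), histones (-0.08, percentile 61.4) and photosynthesis genes, a marker of shoot tissue (-0.00, percentile 34.03), lay inside the middle 95% of random lists.

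Too few members were measured for a median in 9 lists. ACO1, which makes ethylene, was at least 1.07 higher on the log2 scale in WT ethylene, while ACS2 stood at 0.03. In the list of ERF factors, EREBP1 stood at 0.18, and in that of wall-modifying XTH enzymes XRT5 stood at -0.22. The gibberellin oxidases 20ox2 and GA20OX3 stood at 1.09 and 0.52. Of 12 seed markers on the array only GLUA-2 reached T, with a signal of 90.9 in WT air and 173 in WT ethylene. SAUR and LOB domain genes had 1 member each on the array and 0 measured, and the pectin enzyme and root cortex lists had 0 members.

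In total 1809 of 25935 measured probe sets were at least 2-fold higher and 706 at least 2-fold lower in WT ethylene, and the log2 ratios had an SD of 0.67 across probe sets. Of genes with a second probe set whose first was at least 2-fold apart, 173 of 185 showed the same sign in the second. Each value rests on 1 array per treatment, and the actin 3' to 5' ratio was higher in ethylene.

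In mhz2 roots, fewer genes differed between ethylene and air than in WT. Genes with no usable name were among the largest changes, with LOC4344999 at log2 3.46, LOC4337187 at 2.99 and LOC9268400 at -3.16. Among genes with a name, ADC2 was 8.99-fold lower in ethylene, near its WT value, and CRSH2 3.97-fold lower. ARGOS, an organ-size gene, was 3.28-fold higher against 7.21-fold in WT, YSL15 2.61-fold higher, COPT1, a copper transporter, 2.36-fold, the alcohol dehydrogenase Adh2 2.36-fold, OC-X 2.08-fold, LPR4 2.10-fold, HIRL2 2.09-fold and NAS1 2.06-fold. Among single jasmonate repressor genes, TIFY11A was 3.61-fold lower in mhz2 ethylene, JAZ8 3.56-fold, JAZ11 3.24-fold and JAZ12 3.08-fold. BHLH148 was 3.66-fold lower, HSF07 3.46-fold, PAL06, a phenylalanine ammonia-lyase, 3.02-fold, and the metallothionein MT2C 4.33-fold. The actin gene AC3 (log2 1.18) and the proteasome gene RPT1A (log2 0.97) were higher. The actin 3' to 5' ratio was lower in mhz2 ethylene than in mhz2 air, opposite to WT.

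The lists in mhz2 were partly those of WT and partly opposite to them. Iron uptake and chelation had a median of 0.43, above all random lists, with 12 of 13 members higher. The ethylene signalling list had a median of 0.25 (percentile 99.9), with ETR2 at 0.96, ERS2 at 0.30, ERS1 at 0.29 and EIL1B at -0.81. The LEA and dehydrin list had a median of -1.06, below all random lists, with RAB21 at -1.91 and LEA19 at -1.39. The jasmonate list had a median of -0.53, below all random lists, with 9 of 26 members at least 2-fold lower. WRKY factors had a median of -0.45 (percentile 0.66), pathogenesis-related genes -0.24 (percentile 0.26) and NAC factors -0.25 (percentile 1.45). Type-A response regulators had a median of 0.33 (percentile 99.8), and nitrogen transporters 0.20 (percentile 98.8). Germin-like genes (0.02), cell cycle genes (-0.00) and ABA metabolism (-0.17) lay inside the middle 95% of random lists. In total 125 of 25631 measured probe sets were at least 2-fold higher and 333 at least 2-fold lower, with an SD of 0.32.

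In mhz8 roots, the number of genes that differed between ethylene and air lay between those of mhz2 and WT. Genes with no usable name were among the largest changes, with LOC4344999 at log2 3.17, LOC4340513 at 3.01 and LOC4346054 at -2.94. Among genes with a name, ADC2 was 12.2-fold lower in ethylene, RAB21 4.63-fold by its brightest probe set, Chib3H-h 3.60-fold, CRSH2 3.26-fold, LEA19 3.16-fold and EX2 3.13-fold. TIFY11A was 3.08-fold lower, JAZ8 2.90-fold, LTR1, a MYB factor, 2.57-fold and CML15 2.30-fold. The homeobox gene WOX6 was 4.87-fold higher, OC-X 4.53-fold, ADIPOR1 3.99-fold, ARGOS 3.56-fold, CAD8C 3.50-fold, the laccase LAC7 3.49-fold, the chlorophyll breakdown gene SGR 3.48-fold, the sugar transporter SWEET6A 3.39-fold, YSL15 3.04-fold and BGLU34 2.73-fold. DXPS, by contrast, was 2.07-fold higher and GLP2 1.72-fold. All 14 iron genes were higher, with a median of 0.74 above all random lists, and germin-like genes had a median of 0.52 (percentile 99.96) with 6 of 7 higher. The LEA and dehydrin list had a median of -0.57 (percentile 0.01) and the jasmonate list -0.27, below all random lists. Ethylene signalling (0.25, percentile 97.4) had ETR2 at 1.10, ERS2 at 0.70 and ERS1 at 0.49. Auxin response factors had a median of 0.29 (percentile 99.8), CASP and CASP-like genes 0.30 (percentile 99.9) and fermentation genes 0.41 (percentile 99.7). Cell cycle genes (-0.00) and ABA metabolism (-0.08) lay inside the middle 95%. In total 430 of 25652 measured probe sets were at least 2-fold higher and 153 at least 2-fold lower, with an SD of 0.37. The actin 3' to 5' ratio was higher in mhz8 ethylene than in mhz8 air.

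**Figure D1:**
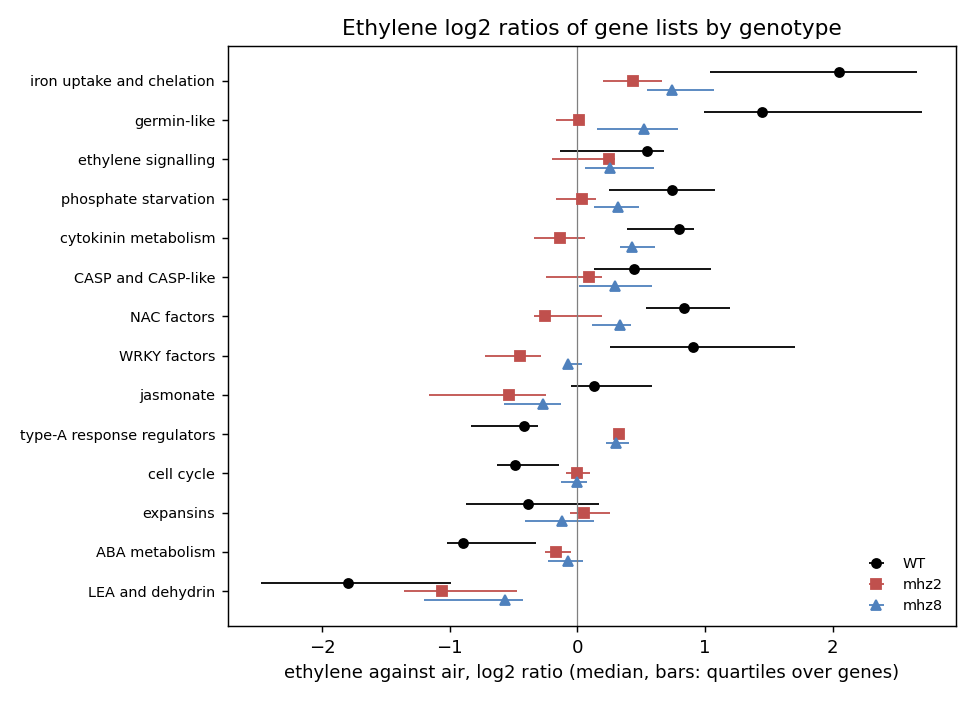
Log2 ratio of ethylene to air for 14 gene lists in WT (circles), mhz2 (squares) and mhz8 (triangles); each symbol is the median over a list's measured genes and the bars are the quartiles over those genes, with 1 array per group. Iron genes lay at 2.05, 0.43 and 0.74 and LEA and dehydrin genes at -1.80, -1.06 and -0.57 in the 3 genotypes, while the jasmonate list lay at 0.13 in WT and at -0.53 and -0.27 in the mutants.

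ADC2, CRSH2, the dehydrin RAB21 and LEA19 were lower, and Adh2, ARGOS, ETR2 and YSL15 higher, in ethylene in each of the 3 genotypes. In an additive limma fit, where the genotypes stood as the repeats of the treatment, ADC2 had the smallest adjusted p, 0.0807, with an average log2 change of -3.43 ± 0.14 (SE), and Adh2 had a change of 1.14 ± 0.08 (SE, limma adjusted p = 0.119). LOC4338151, which has no usable name, had a change of 2.51 ± 0.14 on 1 of its probe sets (SE, limma adjusted p = 0.0863). No probe set of 25805 passed an adjusted p of 0.05 in limma, while 2736 had an unadjusted p under 0.05 where 1290.25 would by chance. Adjusted over the list alone, 3 of 7 ethylene signalling genes rose (ETR2, ERS1 and ERS2), 8 of 14 iron genes rose, among them NAS1 and YSL15, and 5 of 7 LEA and dehydrin genes fell (RAB21, LEA19, RAB16D, RAB16C and RAB16B), each beside 0 over all genes. Adjusted over the list alone, EXPB7 rose and EXPA1, EXPA5 and EXPB9 fell among 24 expansins, AMT3-3, NRT2.3 and NRT2.2 rose among 9 nitrogen transporters, TIFY11A and JAZ13 fell among 27 jasmonate genes, and CH6 and Cht6 rose among 9 pathogenesis-related genes. The same adjustment passed Adh2 among 6 fermentation genes, CAD8C among 19 lignin genes, CKX5 among 8 cytokinin metabolism genes, 20ox2 among 2 gibberellin genes and NAC2 among 6 NAC factors (all higher), and NAC45 (lower). Over all genes 0 of these passed. GLUA-2, the only seed marker tested, had an average log2 change of 0.53 (unadjusted p = 0.0361, adjusted p over all genes = 0.458). Members named here that are no part of the fixed naming rule, such as JAZ13 or EXPA1, were chosen after their values were seen. With the WT arrays left out the limma fit called 68 probe sets higher and 75 lower, and with the mhz2 arrays left out 17 higher and 8 lower.

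The size of the response set WT apart from the mutants. GLP2 rose more in WT than in the mutants by log2 3.81 ± 0.29 (SE; limma adjusted p = 0.0260), DXPS by 4.43 ± 0.56 (adjusted p = 0.0379), JAMYB by 3.04 ± 0.28 (adjusted p = 0.0309) and NAAT1 by 2.39 ± 0.20 (adjusted p = 0.0275). The difference was also positive for GH3.2 (1.95), Lsi1 (1.92), NAS2 (1.86), YSL15 (1.79) and NAS1 (1.68). JAMYB in WT air was below T, so its difference is measured from T. The difference was negative for ILI2 (-2.94, with WT ethylene below T), ILI6 (-2.36), Hox28 (-2.15), ACA5 (-1.96) and RR9 (-1.30). CPS4 (4.11, adjusted p = 0.0653) and PBZ1 (3.03, adjusted p = 0.0652) did not pass. This limma term compares the WT response with that of the mutants taken as alike and has 1 residual degree of freedom. In the simulation at a log2 change of 2 it made 26 false calls beside 108 true ones, so its adjusted p-values may be too small. It passed for 246 probe sets with a higher and 62 with a lower response in WT. The count was 0 with quantile normalization, with no intensity trend, or with 1 floor for all arrays. Adjusted over the list alone, 11 of 14 iron genes (5 over all genes), 14 of 27 jasmonate genes (2 over all), 5 of 7 germin-like genes (2 over all) and 4 of 9 pathogenesis-related genes (1 over all) had the higher response in WT. Over all measured jasmonate genes the median was 0.13 in WT, -0.53 in mhz2 and -0.27 in mhz8, so lower levels in mutant ethylene are part of that difference. Some of the 14 also rose in WT, with OPR-1 at 2.21 and JAZ12 going from a signal of 168 to 567. JAZ12 fell from 819 to 266 in mhz2 and from 1017 to 676 in mhz8. Of the 27 in WT, 4 were at least 2-fold higher and 2 at least 2-fold lower. In air the list already stood higher in both mutants than in WT. Also adjusted over the list alone, 4 of 6 type-A response regulators (1 over all), 4 of 7 ABA metabolism genes (0 over all) and 4 of 7 LEA and dehydrin genes (0 over all) had the lower response in WT. The response of mhz2 against the other genotypes passed for 0 probe sets in limma (1438 at an unadjusted p under 0.05) and that of mhz8 for 0 (94 at an unadjusted p under 0.05). By chance 1290.25 would have an unadjusted p under 0.05. These terms take WT and the remaining mutant as alike, so any difference between those enters the error. The WT and mhz2 responses correlated at only 0.09. The counts of 0 therefore cannot show that mhz2 or mhz8 had no response of its own.

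Genes chosen in a genotype left out of the comparison had larger median increases in WT than in the remaining mutant. The 430 probe sets higher in mhz8 ethylene had a median log2 ratio of 1.83 in WT and 0.46 in mhz2. The 125 higher in mhz2 had medians of 1.76 in WT and 1.27 in mhz8. The 1809 higher in WT had medians of 0.56 in mhz8 and 0.04 in mhz2. Decreases did not follow that order when all chosen probe sets were taken. The 153 probe sets lower in mhz8, which include ADC2 and TIFY11A, had medians of -0.67 in WT and -1.08 in mhz2. The 333 lower in mhz2, which include JAZ8, JAZ11 and JAZ12, had medians of 0.03 in WT and -0.51 in mhz8. Part of these, 49 and 180, were at least 2-fold higher in both mutants than in WT in air. A mutant air array enters both choices with opposite signs, so this overlap is partly built in. Without the 49, WT minus mhz2 had a median of -0.56 over 104 probe sets (quartiles -1.52 and 0.21). Leaving out probe sets by mutant air against WT air lowers this difference by construction, since the same air arrays enter it. The shift towards a larger fall in WT is therefore no result about the genotypes. Without the 180, WT minus mhz8 had a median of 0.32 (quartiles -0.45 and 1.43). The 706 lower in WT had medians of -0.38 in mhz8 and -0.02 in mhz2. Across 22674 probe sets measured on all 6 arrays, the ethylene responses correlated at r = 0.64 between WT and mhz8, 0.34 between mhz2 and mhz8 and 0.09 between WT and mhz2. Probe sets are not independent replicates, so these values carry no p. The WT and mhz8 comparisons shared 366 higher probe sets where independent lists would share 29.5, and 59 lower where they would share 3.60. WT and mhz2 shared 84 higher against 8.43 and 49 lower against 8.37, and mhz2 and mhz8 shared 77 higher against 2.13 and 80 lower against 2.0002. These pairs of comparisons have no array in common.

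**Figure D2:**
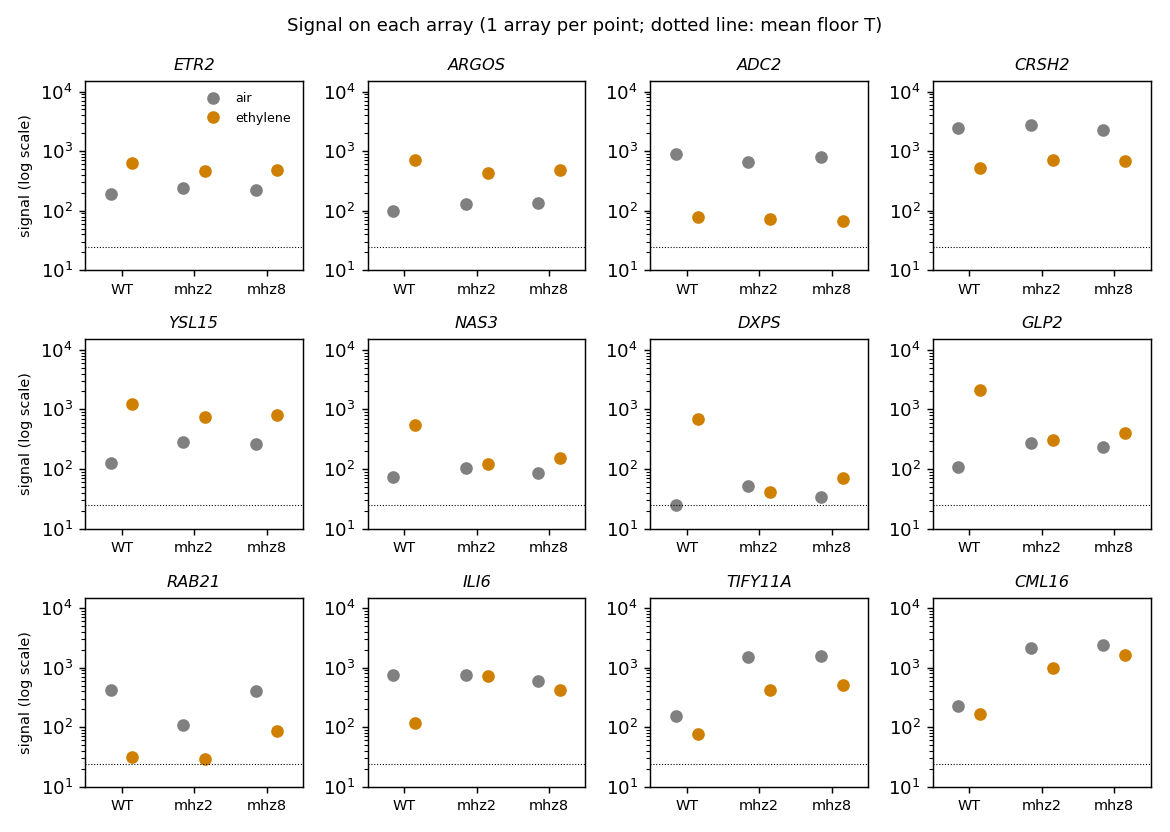
Array signal (log scale) of 12 genes in air (grey) and ethylene (orange) for WT, mhz2 and mhz8, 1 array per point; the dotted line is the mean floor T. ETR2 and ARGOS were higher and ADC2 and CRSH2 lower in ethylene in each genotype, DXPS was 27.9-fold higher in WT and 2.07-fold in mhz8, and CML16 lay at 2170 and 2358 in mutant air against 232 in WT air.

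In air, the named genes furthest above WT in both mutants included single calmodulin-like, jasmonate repressor, trehalose 6-phosphate phosphatase and cold-response genes. The calmodulin-like gene CML15 was 10.3-fold higher in mhz2 and 10.1-fold in mhz8, and CML16 9.36-fold and 10.2-fold. The trehalose 6-phosphate phosphatase gene TPP7 was at least 10.2-fold and at least 10.1-fold higher, and TPP1 5.07-fold and 6.01-fold. TIFY11A was 9.69-fold and 9.95-fold higher, BHLH148 8.45-fold and 9.58-fold, and JAZ12 4.89-fold and 6.07-fold. The cold-response factor CBF3 was at least 8.36-fold higher in mhz2 and at least 7.64-fold in mhz8, DREB1B 7.57-fold and 5.25-fold, HSF07 at least 5.28-fold and at least 7.57-fold, and BC1L9 at least 4.38-fold and at least 8.13-fold. Decreases were smaller. PM1 was 3.81-fold lower in mhz2 and 2.54-fold in mhz8, and P5CS2, which makes proline, had signals of 206 in mhz2 and 237 in mhz8 against 475 in WT. In mhz2, RAB21 was 3.91-fold lower, RAB16D 3.42-fold, OsC3H35 2.49-fold and RPT1A 1.94-fold, with log2 ratios of -0.95 for MADS27, -0.90 for PP2C68, -0.87 for EXPA31 and -0.86 for CH16. In mhz8, the auxin efflux carrier gene PIN2 was 3.39-fold lower against 1.31-fold in mhz2, MT2B 2.23-fold, Hox28 2.22-fold, BGLU10 2.05-fold, and Hox22, BHLH172 and OsCASPL2B1 had log2 ratios of -0.97, -0.97 and -0.95.

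The jasmonate list had medians of 0.45 in mhz2 and 0.39 in mhz8, both above all random lists, with 23 of 25 and 24 of 27 members higher. WRKY factors had medians of 1.08 in each mutant (percentiles 99.98 and 99.97), NAC factors 0.53 and 0.89, germin-like genes 0.51 and 0.41, and lignin and phenylpropanoid genes 0.28 and 0.11 (percentiles 99.99 and 99.9). Type-A response regulators had medians of -0.56 and -0.62, below all random lists, with RR9 at -0.86 and -0.85. The LEA and dehydrin list had a median of -1.06 in mhz2, below all random lists, and -0.23 in mhz8 (percentile 4.23). Ethylene signalling had medians of -0.10 and -0.07, and iron genes 0.05 and -0.04, inside the middle 95%. In total 666 of 25622 measured probe sets were at least 2-fold higher and 116 lower in mhz2, and 672 of 25643 higher and 124 lower in mhz8. The mutant air arrays were close to each other, with r = 0.994 across probe sets and 29 probe sets at least 2-fold apart. Their actin 3' to 5' ratios were both above that of WT air.

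In ethylene, both mutants had lower levels than WT of the iron and germin-like lists and of single genes that were high on the same WT array. CYP99A3 had log2 ratios to WT of -4.73 in mhz2 and -3.76 in mhz8, CPS4 -4.50 and -3.54, DXPS -4.07 and -3.31, MT2C -4.70 and -3.03, NAAT1 -2.94 and -2.74, and GLP2 -2.77 and -2.39. The iron list had medians of -1.43 and -0.83 and the germin-like list -1.73 and -1.35, all below all random lists. Cell cycle genes had medians of 0.39 (percentile 99.99) and 0.30 (percentile 99.9), and cellulose synthases 0.42 (percentile 99.9) and 0.38 (percentile 99.99). Of the probe sets at least 2-fold higher in both mutants in air, 16.9% in mhz2 and 44.7% in mhz8 were at least 2-fold higher than WT in ethylene too. CML16 stood at 2.60 in mhz2 and 3.34 in mhz8 and TIFY11A at 2.44 and 2.71, while JAZ12 had signals of 266 in mhz2 and 676 in mhz8 against 567 in WT. In total 529 of 25968 measured probe sets were at least 2-fold higher and 1236 lower in mhz2, and 453 of 25697 higher and 734 lower in mhz8.

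**Figure D3:**
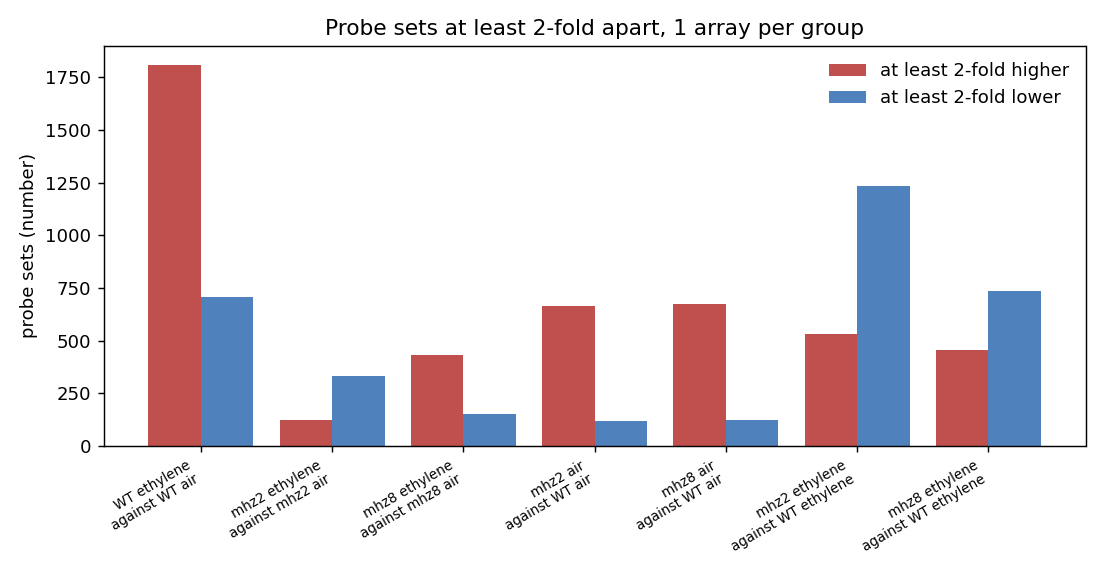
Number of probe sets at least 2-fold higher and at least 2-fold lower in each of 7 comparisons, with 1 array per group. By the total of higher and lower, WT ethylene against WT air had the most, 2515, and mhz2 ethylene against mhz2 air the fewest, 458.

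Averaged over air and ethylene, which stood as repeats of each other in the limma fit, 5 probe sets rose in mhz2 and 11 in mhz8, and 0 fell in either. With a floor at 0.4 of the trimmed mean 1 probe set rose in mhz2, and with no intensity trend 7 rose in mhz8. The unadjusted p was under 0.05 for 670 lower probe sets in mhz2 and 742 in mhz8. The 5 of mhz2 were chosen after their values were seen and are among the 11 of mhz8: LOC4331398 (log2 4.13 ± 0.16 SE, adjusted p = 0.0295), LOC4326189 (3.45), LOC9268308 (3.70) and 2 probe sets with no listed gene (5.26 and 3.53). LOC4331398 had signals of 5.26 and 7.04 on the WT arrays, below T, and of 360 to 471 on the mutant arrays, and LOC4326189 had 4.45 and 6.32 against 261 to 359, so their log2 changes are measured from T. LOC9268308 was below T in WT air, with a signal of 15.6, so its change is measured partly from T. Of the named genes CML16 passed in mhz8, with 3.34 ± 0.20 (SE, adjusted p = 0.0433). Adjusted over the list alone, 8 of 27 jasmonate genes rose in mhz8 and 3 in mhz2 (0 over all genes in each), among them TIFY11A and AOS1 in both. Also over the list alone, CESA4, CESA7 and CESA9, known for secondary walls, rose in both mutants among 14 cellulose synthase genes, and CSLD2 in mhz8 (0 over all genes). Single genes passed in the same way in other lists, with 0 over all genes: ABA8OX1, NAC45 and NRT2.3 rose in both, NRT2.2, Cht6 and wrky38 rose in mhz8, CH16 fell in both, CH6 fell in mhz2, and PIN2 and IAA25 fell in mhz8.

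The mutants were each compared with the same WT array, so their differences share its chance values. In air, 528 probe sets were at least 2-fold higher in both mutants where independent lists would share 17.4, and 64 were lower in both against 0.570. In ethylene, 209 were higher in both against 9.09 and 661 lower in both against 35.7. The mutant effects correlated at r = 0.87 in air (covariance 0.129) and 0.81 in ethylene (covariance 0.199), where unchanged groups simulated against a shared array gave r = 0.50 (covariance 0.0480). Part of the excess may come from the shared array, which could not be split. Taken from different treatments, with no array in common, the effects of mhz2 in air and mhz8 in ethylene correlated at 0.24, and those of mhz2 in ethylene and mhz8 in air at -0.00346. The effects of a mutant in air and in ethylene, which the average over treatments takes as repeats, correlated at -0.0772 in mhz2 and 0.295 in mhz8.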

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

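All tests of explanations in this part were chosen only after the results were seen. The response to ethylene differed between WT and the mutants for 308 probe sets in the limma interaction test, which takes the mutants as alike. That count was 0 with quantile normalization, with no intensity trend and with a single floor, and 11 higher and 3 lower with a floor at 0.4. Other results stood out because mhz2 or mhz8 moved opposite to WT in ethylene. The difference between WT and a single mutant was not tested. Pathogenesis-related genes had a list median of -0.24 in mhz2 against 0.41 in WT. The jasmonate list had -0.53 in mhz2 and -0.27 in mhz8 against 0.13 in WT. NAC factors had -0.25 in mhz2 against 0.84, and WRKY factors -0.45 in mhz2 against 0.91. Among single genes, the actin gene AC3 had a log2 ratio of 1.18 in mhz2 and signals of 167 in air and 83.7 in ethylene in WT, CYP99A2 had a log2 ratio of -1.11 against at least 3.38, JAZ12 -1.62 against 1.76, MT2B -1.55 against 2.01, MT2C -2.11 against 2.42 and OPR10 -1.32 against 1.33. In the limma test of WT against both mutants, JAZ12 passed (2.87, adjusted p = 0.0446), and AC3 (adjusted p = 0.387), CYP99A2 (0.182), MT2B (0.214), MT2C (0.128) and OPR10 (0.111) did not.

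The first pattern weighed is the larger ethylene response in WT. Probe-level noise of the WT arrays would leave second probe sets of the same genes without a common sign, yet 93.5% of them had the sign of the first; both read the same RNA, so a difference between the single WT samples that is not due to ethylene stays open. RNA integrity as the whole cause is argued against for mhz8, where the 3' to 5' ratios of actin, Gapdh and cyclophilin changed by log2 1.09, 0.90 and 0.20 from air to ethylene, each by as much as in WT or more, with 454 probe sets at least 2-fold apart against 2091 in WT; for mhz2, with 350, integrity and genotype cannot be told apart, since its actin ratio changed less than that of WT (-0.77) and its Gapdh and cyclophilin ratios more (-0.52 and -0.30). A weaker rise in mhz2 would put probe sets chosen in mhz8 further up in WT than in mhz2, as 93.3% of those higher in mhz8 were. The actin, Gapdh and cyclophilin ratios rose in WT and mhz8 and fell in mhz2, so integrity could give this too. A weaker rise in mhz8 stays open. Of the probe sets higher in mhz2, 60% were further up in WT than in mhz8, and the quartiles of the difference were -0.43 and 0.99. Weaker falls in the mutants stay open too. With probe sets higher in both mutants in air left out, for those lower in mhz2 WT minus mhz8 had a median of 0.32 with quartiles of -0.45 and 1.43. For those lower in mhz8, WT minus mhz2 had a median of -0.56 with quartiles of -1.52 and 0.21. The probe sets left out were chosen on the same air arrays that enter the difference. That lowers it by construction, so these medians cannot decide the question.

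The second pattern is the 528 probe sets higher in both mutants in air, with CML15, CML16, TIFY11A and TPP7 among the largest. A low WT air array alone is argued against for mhz8, whose median for these probe sets against WT in ethylene, where that array is not used, was 0.92 with quartiles of 0.40 and 1.43. For mhz2 the same median was 0.26 with quartiles of -0.30 and 0.81, so there the WT array and a genotype effect in air cannot be told apart. RNA integrity was not tested for these probe sets and stays open. The actin 3' to 5' ratio lay above WT in mhz2 air (8.98) and mhz8 air (6.36 against 4.90). In ethylene it lay above WT in mhz8 (13.5 against 9.79) and below in mhz2 (5.28). The cyclophilin ratio of mhz8 was not above WT in air (2.26 against 2.39) or ethylene (2.61 against 2.65). Handling of the mutant seedlings before harvest and a genotype effect also cannot be told apart, since 44.7% of these probe sets were at least 2-fold higher in mhz8 than WT in ethylene, a share that a lasting genotype effect or handling of several samples could both give. Of the 333 probe sets lower in mhz2 ethylene, 180 belong to this set, and the other 153 had medians of -0.01 in WT and -0.38 in mhz8. Both choices use the mhz2 air array with opposite signs. A high chance value on that array would put a probe set in both, so this overlap is partly built in.

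The third pattern is the lower dehydrin transcripts in ethylene. A high WT air sample alone is argued against by the mutants, whose list medians were -1.06 in mhz2 and -0.57 in mhz8, both below the middle 95% of random lists. Seed tissue that carries the seed markers used is argued against in the air samples, since 1 of 12 markers reached T in WT air. That was GLUA-2 with 90.9, and it was higher in WT ethylene at 173. In mhz2 and in mhz8, 1 of 12 was measured over air and ethylene. Seed tissue without these transcripts is not covered. The lower water level that the labels give for ethylene may act on these ABA-related genes as well as ethylene itself, and no array tests it.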

How the results depend on the processing

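One alternative, a single floor for all arrays, was chosen after seeing the data; the others were planned. All 70 alternative counts of 2-fold differences, 15 correlations and 60 medians in the remaining genotypes stayed within the tolerances set, as did all 449 list medians; 2-fold counts in WT ethylene ran from 1380 to 2103 higher and 573 to 802 lower. No scaling moved the median of all probe sets by over 0.1. The limma counts moved most. For the WT response, quantile normalization gave 0 higher and 0 lower, no intensity trend 0 and 0, a single floor 0 and 0, and a floor at 0.4 gave 11 and 3, against 246 and 62. The prior degrees of freedom that limma estimated were 3.30, 3.92, 3.50 and 4.33 in the same order, against 5.04; the cause was not tested. The floor at 0.4 left 1 higher probe set in mhz2, and no trend left 7 in mhz8. Without the filter, limma called 2496 higher and 1468 lower for ethylene, 1068 and 1660 for mhz2, 1210 and 1547 for mhz8, and 2593 and 1787, 386 and 1020, and 435 and 634 for the responses of WT, mhz2 and mhz8. There, probe sets at T on every array have a spread set by T alone, and the prior degrees of freedom became infinite, so the spread of each probe set no longer entered its own test; 0 of the probe sets called were at T on every array. The average ethylene effect gave 68 higher and 75 lower without the WT arrays and 17 and 8 without the mhz2 arrays; without mhz8 it gave 0. Each of these fits has 1 residual degree of freedom, and the cause was not tested. Of all 211 alternatives other than list medians, 185 were unchanged by the tolerance or threshold set for them. These 185 include the counts of 2-fold differences, correlations and medians above, and all changes were in limma counts. In the additive fit for ethylene, the real split of the 6 arrays into 3 and 3 gave 0 probe sets, the highest other being 1. All 10 splits gave at least as many as the real one, but a count of 0 fixes that in advance, so the splits decide nothing. With 10 splits, a share under 0.05 is also out of reach. Within a genotype no pairing of replicates was possible, because each group has only replicate number 1. The additive fit, with genotype as a block, pairs each ethylene array with the air array of its genotype. Between 42.9% and 43.5% of probe sets per array reached T, and changes among signals below T are not seen.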

Other observations

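The lists in this part were chosen only after values were seen. Several plastid isoprenoid and diterpenoid phytoalexin genes were high in WT ethylene. Of 15 diterpenoid phytoalexin genes 8 were measured, 6 of them at least 2-fold higher in WT, while CYP76M8 stood at 0.19 and CYP76M6 at -0.17. The median log2 ratio was 2.01 in WT, -0.62 in mhz2 and 0.44 in mhz8. The list was made because CPS4, CYP99A3 and CYP99A2 had been seen among the largest WT ratios, so its rank among random lists is not a test. OsMAS, a momilactone synthase, stood at 2.26 in WT and -0.71 in mhz2. The methylerythritol phosphate pathway, which supplies their precursors, had 6 of 7 measured genes at least 2-fold higher in WT, with CDPMEK at 1.82, ISPG at 1.78, ISPF at 1.58, ISPH at 1.54 and DXR at 1.16. Its medians were 1.58 in WT, -0.34 in mhz2 and 0.22 in mhz8. ISPG passed the limma test of a larger response in WT (log2 1.91, adjusted p = 0.0309), as did DXR (1.60, adjusted p = 0.0414), OsMAS (2.63, adjusted p = 0.0460) and DXPS (4.43, adjusted p = 0.0379). It did not pass for ISPH (adjusted p = 0.0653), ISPF (0.0774), CDPMEK (0.101), CPS4 and CYP99A3 (0.0653 each), CYP701A8 (0.0550), DTS2 (0.161), CYP99A2 (0.182), CYP76M8 (0.776) or CYP76M6 (0.833). With quantile normalization, no intensity trend or a single floor, 0 probe sets passed that test.

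Metallothioneins were also high in WT ethylene, with a median of 1.95 and 5 of 7 at least 2-fold higher, against 0.04 in mhz2 and 0.78 in mhz8. The mhz2 value hides 2 groups, since MT4A (0.96), MT-1-4b (0.83) and MT1B (0.58) were higher in mhz2 ethylene, and MT2C (-1.68 by its brightest probe set), MT2B (-1.55) and MT-2 (-0.70) lower. MT2B and MT2C carry each other's synonyms in the name table, and which name belongs to which was not settled here. In the mutants in air, calmodulin-like genes had medians of 0.24 in mhz2 and 0.12 in mhz8, with 3 of 21 and 3 of 20 at least 2-fold higher, CML15, CML16 and CML31. Trehalose 6-phosphate phosphatases had medians of 0.37 and 0.37, with 2 of 7 in mhz2 and 3 of 7 in mhz8 at least 2-fold higher. DREB1 factors had medians of 1.50 over 4 genes and 0.52 over 5, with only DREB1B and CBF3 at least 2-fold higher in each.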
